A study of Arabidopsis thaliana with 3 samples.

How the data were processed

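RNA of whole Arabidopsis thaliana seedlings was measured by sequencing in 3 groups: untreated wild type, salt-treated wild type and salt-treated skip mutant. The labels give total RNA extracted with Trizol and libraries made by a standard Illumina protocol. They do not give the library kit, the selection of RNA, the strand setting or the read length, which are not given in the sources used here. Each label merges replicate 1 and replicate 2 of its group, and the way in which the 2 replicates were combined is not given in the sources used here either.

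The values came from 2 tables of the whole series, which list the same 33557 gene identifiers. The first pairs untreated with salt-treated wild type, and the second pairs salt-treated wild type with salt-treated skip. The deposited values were read as FPKM, fragments scaled to transcript length and library size, with 1 value of the authors per gene and group. The tables state no unit, and FPKM was inferred from the values and from the tools named. TopHat, a spliced aligner, Cufflinks, which estimates transcript levels, and the TAIR10 genome were used per the submitters' processing notes, which give no version for either tool. Neither a count, a replicate value, an error nor a q-value accompanies the values used here. All 4 value columns were used.

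Salt-treated wild type occurs in both tables. Its values differed by a single factor, with a median ratio of 1.105 over 24882 genes above 0, and 24822 of these lay within 0.1% of that median. The tables were therefore scaled separately, and every ratio was formed within a table. An FPKM of salt-treated wild type is quoted from the table of the comparison in which it stands.

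For each gene the log2 ratio of FPKM + 1 was computed between the 2 groups of a table. This pseudocount of 1 understates the changes of genes with low values, and all fold changes given are on that scale. The planned use of the authors' q-values was not possible, so the rule written for that case was applied: a gene counts as higher or lower when its log2 ratio is at least 1 in size, which is a rule of size (2-fold) and not a test. No filter was applied to low values. An exact 0 in such a table can be a failed estimate, so a gene at 0 is described as listed at 0 and no fold is given.

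Genes were named by a rule fixed before the data were examined. It takes, per comparison, the 10 largest changes in each direction among genes past the 2-fold rule with an FPKM of at least 5 in a group, the 4 largest changes of each gene list, SKIP and the reference genes, and 5 genes per direction with opposite changes in the 2 comparisons. Outside this rule, COR15A, AZF1, AZF3, SOS1, SOS2, HAK5, SCR, SHR and AT2G01010 were named for salt, and RD29A, RAB18, RD20, EM1, CBF4, WRKY25, SOS1, SOS2, RVE8, FLC, MAF2, MAF3, BHLH92 and AT2G01021 for skip, after their values had been seen. The 22 lists, with 289 genes, were fixed at the same time and all 289 were in the tables. They cover stress and hormone pathways, splicing factors, photosynthesis, the clock, flowering, and marker genes of root and seed, and 1 of them is SKIP alone. A list is described by the members past the rule, its median log2 ratio with a 95% interval of the median over members from binomial order statistics, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean expression. The interval describes the spread over genes and not the error between plants.

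Names, exon numbers, lengths and GC content came from the RefSeq annotation of assembly TAIR10.1, which matched 32810 of the 33557 identifiers. Since that assembly differs in name from the authors' build, no coordinates are given. A group of 1890 features was left out where stated: loci of the organelle genomes, loci annotated as rRNA, and genes whose longest transcript is under 300 nt. For list members, named genes and other leading genes, the share of the longest transcript's 50-mers that also occur in another gene was computed. It was at least 20% for 22 of the 289 list genes. Both strands were counted, and loci that overlap a gene at the same place were not left out. The share therefore mixes copies elsewhere with overlapping annotation, and for these genes it only marks values that may include reads of another locus.

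The depth was estimated from the low values. For genes with a single transcript longer than 800 nt, FPKM times effective length clustered at steps of 0.02155 in untreated wild type, 0.02145 and 0.01945 in salt-treated wild type (first and second table), and 0.02685 in skip. Of the values between 0.5 and 3.5 steps, 44.4%, 68.5%, 68.5% and 65.0% lay within 0.15 of a whole number of steps, against 30% by chance. Whole reads were therefore not recovered for nearly all genes and no count test was run. Taking a step as 1 fragment, a gene of 1 kb effective length at 5 FPKM rests on about 232, 233, 257 and 186 fragments in the same order. These are estimates, and they cover counting error only.

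The rule was tested on simulated data in which fragments were drawn at that depth for 32802 genes. The 200 changed genes were drawn only from genes of at least 5 FPKM in the first group of the pair. In each comparison 2 unchanged genes passed the rule as higher and 3 as lower, all 50 genes changed 3-fold, all 50 changed 4-fold and all 50 changed 8-fold were recovered, and 0 of the 50 changed 1.5-fold passed. At such levels the depth nearly fixes which of these changes pass a 2-fold rule, so the recovery does not cover genes of lower values. Variation between plants was not part of the simulation. Of random lists, 7.5% fell outside the central 95% of matched lists in the salt comparison and 2.5% in the skip comparison.

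Alternatives were pseudocounts of 0.1 and 0.01, minimum FPKM of 1 and 5, centring on the median gene, unmatched random lists and, chosen after seeing the data, leaving out the special features above or the genes listed at 0, and centring within exon classes. Intervals of differences between gene classes came from 1000 bootstrap draws over genes, or 200 for the estimate binned by length and GC. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.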

Results

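Seedlings of Arabidopsis thaliana, 11 days old, were kept for 4 h in MS liquid medium, a standard plant medium, or in the same medium with 200 mM NaCl. Wild type was measured without and with salt, and the skip mutant with salt. SKIP (AT1G77180) encodes a protein of the spliceosome that also works with the Paf1 complex in transcription. The title of the series places SKIP in salt tolerance through alternative splicing, while the values analysed here are totals per gene and do not measure splicing. Each group has 1 value per gene in which the authors merged 2 replicates, so no difference below has a replicate check and no p-value is given. Of 33557 genes, 24170 had an FPKM above 0 in untreated wild type, 24882 in salt-treated wild type and 24540 in salt-treated skip. The values give no read totals. Their sums were 851739 and 813581 FPKM for untreated and salt-treated wild type in the first table, and 736286 and 787004 FPKM for wild type and skip with salt in the second, and a transcript of 1 kb at 5 FPKM rested on an estimated 186.2 to 257 fragments, which covers counting error only.

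SKIP itself was listed at 39.2 FPKM in untreated and 54.2 FPKM in salt-treated wild type, a log2 ratio of 0.46. In the second table it was listed at 49.0 FPKM in wild type and 41.6 FPKM in skip, a log2 ratio of -0.23. The labels do not give the allele, so this total neither bears out nor contradicts the genotype. None of the 8 reference genes, which include ACT2, UBQ10 and PP2AA3, passed the 2-fold rule in either comparison. The widest were ACT2 with a log2 ratio of -0.93 for salt and GAPC1 with 0.81 for skip. Their medians were -0.06 (-0.93 to 0.52) for salt and -0.06 (-0.64 to 0.81) for skip, at percentiles 72.4 and 44.5 of matched random lists, and the second turns positive when ratios are centred on the median gene.

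The first comparison asks what 4 h of salt did to wild-type seedlings. All LEA and dehydrin genes, all clade A PP2C phosphatases in signalling by abscisic acid (ABA), a stress hormone, and most stress transcription factors of the fixed lists were higher with salt, while most genes of a list of root markers were lower. In all, 2027 genes were at least 2-fold higher and 1277 at least 2-fold lower with salt, and 704 and 259 of the same directions passed 4-fold. On the scale of FPKM + 1, the largest increases among genes above 0 in both groups included those of transcription factors: RRTF1 (AT4G34410) went from 0.350 to 118.1 FPKM, BHLH92 (AT5G43650) from 0.336 to 106.6 FPKM, HSFA6B (AT3G22830) from 1.80 to 212 FPKM and ERF13 (AT2G44840) from 0.349 to 67.4 FPKM. GOLS2 (AT1G56600), an enzyme of galactinol and raffinose synthesis, was 53.3-fold higher, and AT3G03341, a locus without a symbol, was 58.9-fold higher. Of RRTF1, 59.2% of the sequence is shared with other annotated loci, so its value is less certain.

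LEA proteins and dehydrins, which protect cells during water loss, were higher with salt. Their list keeps this name here although it also holds some stress genes of other kinds, such as RD20. All 19 members were at least 2-fold higher, with a median log2 ratio of 2.75 (2.31 to 3.99), at percentile 100 of matched random lists. RD29A went from 60.2 to 1326 FPKM, COR15A from 309 to 2091 FPKM, LEA4-5 from 16.2 to 549 FPKM and EM1 from 0.362 to 37.5 FPKM. Of 25 stress transcription factors, 23 were higher and 2 were within the rule, with a median of 3.42 (2.57 to 4.37), percentile 100. CBF1 was 43.4-fold, DDF1 38.8-fold, WRKY40 34.8-fold and NAC019 29.5-fold higher. The members within the rule were the zinc finger genes AZF1 (-0.95) and AZF3 (-0.04), of which AZF3 shares 41.2% of its sequence with a neighbouring locus.

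The parts of the ABA pathway moved apart. All 9 clade A PP2C phosphatases, which hold ABA signalling down, were higher, with a median of 3.12 (1.62 to 4.82), percentile 100. HAI3 was 30.4-fold, HAI2 28.3-fold and HAI1 20.9-fold higher, and PP2CA went from 25.2 to 234 FPKM. Of 9 ABA receptors, 4 were lower, 1 was higher and 4 were within the rule, with a median of -0.96 (-2.42 to 0.94), percentile 0.02. PYL4 went from 64.6 to 7.21 FPKM and PYL6 from 6.51 to 0.406 FPKM, while PYL7 went from 17.0 to 48.6 FPKM, although 43.8% of the PYL7 sequence is shared with the neighbouring locus AT4G01030. Among 8 kinases and bZIP factors of the pathway, 5 were higher and 3 within the rule, with a median of 1.102 (0.16 to 2.77), percentile 99.9. ABI5 was 6.82-fold and ABF3 4.56-fold higher. Among 11 genes of ABA synthesis and breakdown, 4 were higher and 7 within the rule, with a median of 0.77 (0.25 to 2.45), percentile 99.95. Both directions of metabolism were among them: NCED3, an enzyme of synthesis, was 15.7-fold higher, and CYP707A3 and CYP707A1, enzymes of breakdown, were 5.45-fold and 4.74-fold higher.

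Ion transport was less uniform. Of 20 genes of ion transport and the SOS pathway, which exports sodium, 6 were higher, 1 was lower and 13 were within the rule, with a median of 0.18 (-0.28 to 1.13), percentile 94.98. CBL1 was 3.73-fold, SOS3 2.66-fold, NHX2 2.55-fold and NHX1 2.48-fold higher, while SOS1 had a log2 ratio of 0.13 and SOS2 of -0.04. HAK5, a potassium transporter, was the lower member at -1.22. Of 12 genes of proline and compatible solutes, 3 were higher and 9 within the rule, with a median of 0.43 (0.23 to 1.301), percentile 98.5. P5CS1, the main enzyme of proline synthesis under stress, was 7.86-fold higher. Of 18 aquaporins, 7 were higher, 2 lower and 9 within the rule, with a median of 0.47 (-0.70 to 1.099), percentile 99.95. TIP2;3 was 4.63-fold and PIP1;4 3.802-fold higher, and PIP2;4 was 2.61-fold lower.

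Many jasmonate and heat shock genes were higher with salt as well, while genes of oxidative stress and pathogenesis were mostly within the rule. Of 16 jasmonate genes, 9 were higher and 7 within the rule, with a median of 1.12 (0.72 to 2.64), percentile 100. The repressors JAZ7, JAZ10 and JAZ5 were 14.6-fold, 9.63-fold and 9.37-fold higher. Of 18 heat shock genes, 9 were higher and 9 within the rule, with a median of 0.9999 (0.42 to 1.81), percentile 100, led by HSFB2A at 6.13-fold. Of 10 genes of oxidative stress, 2 were higher and 8 within the rule, with a median of 0.12 (-0.59 to 1.001), percentile 89.8. APX2 went from 0.0528 to 2.44 FPKM, and RBOHF passed the rule narrowly but not after centring on the median gene. Of 7 pathogenesis-related genes, PR5 and PDF1.2A were 2.42-fold and 2.14-fold lower and 5 were within the rule, with a median of -0.16 (-1.28 to 0.51), percentile 24.2.

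Splicing factors stayed within the rule. Of 20 SR proteins, 0 were higher and 0 lower, with a median of -0.03 (-0.12 to 0.24), percentile 49.9, and of 12 genes of the spliceosome and Paf1 complex, 0 were higher and 0 lower, with a median of 0.05 (-0.06 to 0.25), percentile 58.1. Of 15 clock genes, 5 were higher and 10 within the rule, with a median of 0.65 (-0.10 to 1.21), percentile 99.9. FKF1 was 2.69-fold, RVE1 2.56-fold, PRR9 2.38-fold and ELF4 2.31-fold higher, and PRR9 shares 29.9% of its sequence with another locus. All 11 flowering time genes stayed within the rule, with a median of -0.18 (-0.40 to 0.32), percentile 19.7. All 19 nuclear photosynthesis genes lay below 0 and within the rule, with a median of -0.47 (-0.73 to -0.34). Their percentile was 3.89 among matched lists and 0.09 among unmatched lists.

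Markers of the root were lower with salt. Of 16 root genes, 12 were lower and 4 within the rule, with a median of -1.76 (-2.22 to -0.77), percentile 0. PRP3 and PRP1, cell wall proteins of root hairs, were 12.5-fold and 11.99-fold lower, the phosphate transporter PHT1;1 6.36-fold and the Casparian strip protein CASP2 4.67-fold lower. PHT1;1 shares 42.4% of its sequence with other loci. Transcripts of the root transcription factors SCR and SHR had log2 ratios of -0.24 and -0.77. On the same scale, the largest falls of genes above 0 in both groups included AGP22 (AT5G53250), an arabinogalactan protein of the cell wall, from 46.1 to 1.002 FPKM, EXT13 (AT5G35190), an extensin, from 73.1 to 2.61 FPKM, and GASA6 (AT1G74670), a gibberellin-regulated gene, from 85.0 to 3.26 FPKM. AT4G12520, AT4G12510, AT4G12545 and AT4G22666 were 36.2-fold, 27.0-fold, 22.7-fold and 19.8-fold lower. AT4G12520 and AT4G12510 share 47.3% and 51.8% of their sequence with each other, and AT4G12545 shares 48.4% with other loci, so their values may be split between copies. Of 5 seed storage and oil body genes, CRA1 and CRU3 were 2.603-fold and 2.22-fold lower and 3 were within the rule, all at low levels, with a median of -0.16 (-1.38 to -0.02), percentile 12.7.

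**Figure D1:**
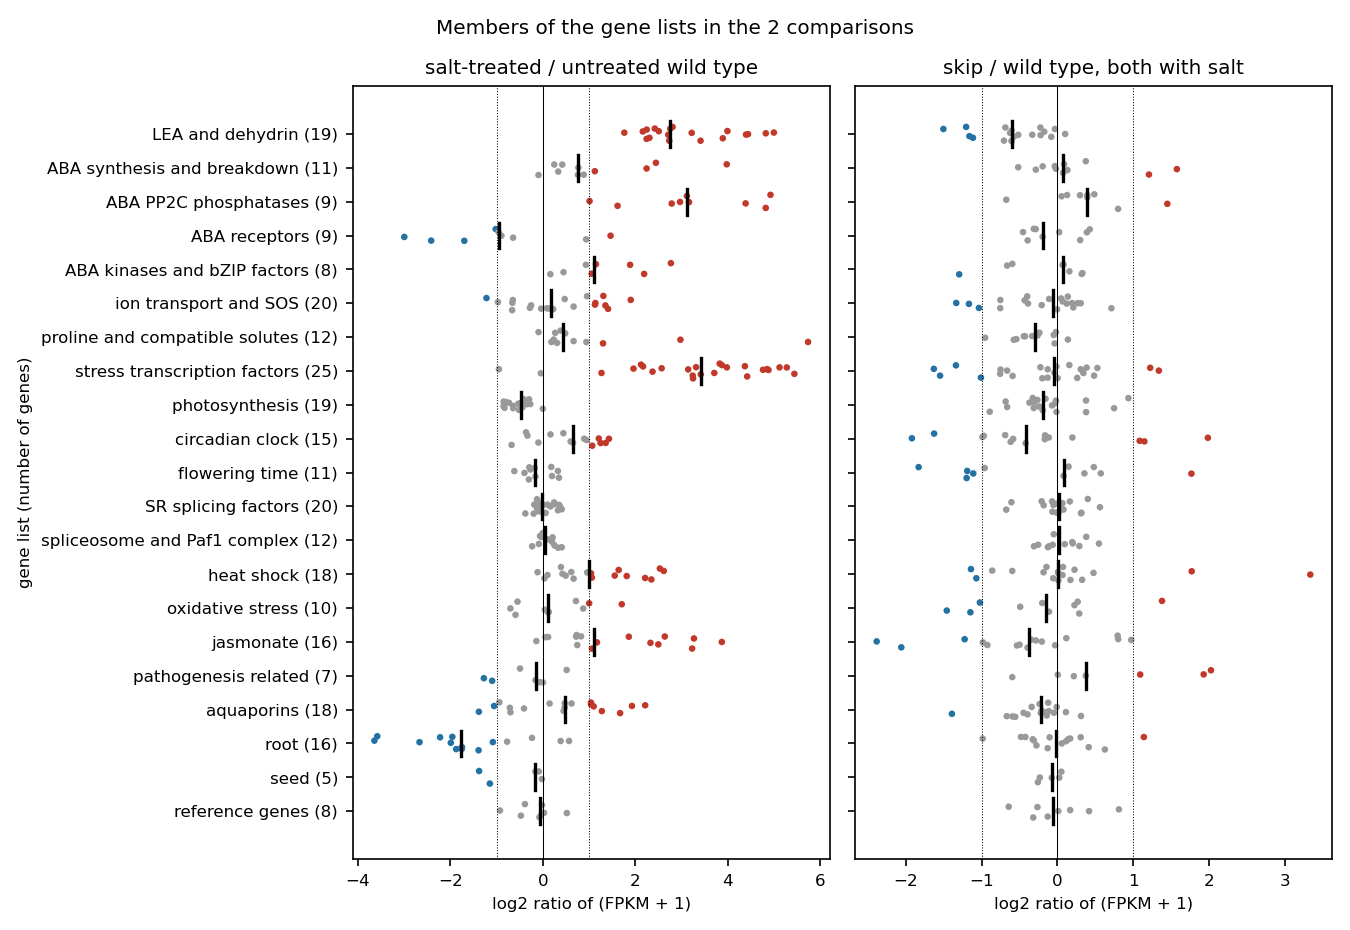
Log2 ratio of FPKM + 1 (horizontal axis) for each member of the gene lists (rows, number of genes in brackets), for salt-treated against untreated wild type on the left and skip against wild type with salt on the right. Points are genes, red at or above 1, blue at or below -1 and grey between, black bars are list medians, and the LEA and dehydrin median is 2.75 on the left and -0.60 on the right.

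Several of the features past the rule are short, non-coding or organellar and are listed at 0 in a group, and their values are uncertain. With salt, the rRNA locus AT3G41768 was listed at 0 and then at 5092 FPKM, while AT2G01010, with which it shares 94.3% of its sequence, went from 13905 to 2587 FPKM. The chloroplast locus ATCG00220 went from 0 to 702 FPKM, the precursor locus MIR397a from 0 to 187 FPKM and the short gene AT5G14560 from 0 to 44.9 FPKM. In the other direction MIR400 went from 2202 FPKM to 0, the chloroplast locus ATCG00065 from 50.2 FPKM to 0 and AT4G37095 from 45.1 FPKM to 0. Of the genes past the rule, 76 higher ones had a 0 without salt and 32 lower ones had a 0 with salt.

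The second comparison asks how skip and wild type differed after the same salt treatment. Without an untreated skip group analysed here, it cannot separate a different salt response from a difference that is there without salt. Compared with wild type, skip had lower levels of several cold- and drought-responsive genes, of jasmonate-responsive storage proteins and of FLC and several related flowering repressors. It had higher levels of a pair of MATE efflux carriers and of most chloroplast and mitochondrial genome loci that were above 0 in both groups. In all, 548 genes were at least 2-fold higher and 875 at least 2-fold lower in skip, and 132 and 74 of the same directions passed 4-fold. Of the genes past the rule, 131 higher and 33 lower ones were organellar, rRNA or short features. The median gene above 5 FPKM in both groups had a log2 ratio of -0.07.

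On the scale of FPKM + 1, the largest rises among genes above 0 in both groups were those of AT2G04050, from 11.9 to 258 FPKM, and AT2G04070, from 1.401 to 38.7 FPKM, which belong to the MATE family of efflux carriers, of AT2G21640, from 12.2 to 240.4 FPKM, of AT4G29200, from 0.0669 to 12.8 FPKM, and of UGT73C6 (AT2G36790), a glycosyltransferase, from 1.88 to 31.0 FPKM. The whole sequence of UGT73C6 is shared with the annotated locus AT2G36792. On that scale the naming rule took BGLU24 (AT5G28510), a beta-glucosidase, as lower, from 70.7 to 3.49 FPKM, while ratios of FPKM itself were wider for some genes that came close to 0 in skip. AT3G02468 went from 102.8 to 1.23 FPKM. It has no entry in the reference used here, so its overlap with neighbouring loci could not be checked and its value is uncertain.

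Most LEA and dehydrin genes had ratios below 0 in skip, and few passed the rule. Of 19 members, 4 were at least 2-fold lower and 15 within the rule, with a median of -0.60 (-0.71 to -0.22), percentile 0 of random lists matched on expression but not on the salt response. In all, 18 of the 19 ratios lay below 0. COR15A went from 1892 to 666 FPKM, COR15B from 432 to 186.9 FPKM, KIN1 from 700.1 to 312 FPKM and LTI30 from 1270.5 to 586 FPKM. RD29A had a log2 ratio of -0.57, RAB18 of -0.17 and RD20 of -0.03, while EM1 lay at 0.10. COR15B shares 27.3% of its sequence with a neighbouring locus. The 25 stress transcription factors split: 4 were lower, 2 higher and 19 within the rule, with a median of -0.04 (-0.59 to 0.31), percentile 54.9. The DREB-type factors CBF3, DDF1 and DREB2A were 3.10-fold, 2.92-fold and 2.53-fold lower and CBF4 had a log2 ratio of -1.01 that was -0.94 after centring, while ZAT7 was 2.53-fold higher and WRKY25 had a log2 ratio of 1.22.

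Few core ABA genes passed the rule, although the PP2C phosphatases lay above 0 as a list. Of 9 PP2C phosphatases, AHG1 was higher, from 1.404 to 5.57 FPKM, 8 were within the rule and 8 of the 9 ratios were above 0, with a median of 0.40 (0.06 to 0.80), percentile 99.8. All 9 ABA receptors were within the rule, with a median of -0.20 (-0.39 to 0.39), percentile 22.7. Of 8 kinases and bZIP factors, ABF1 was lower, from 43.4 to 17.1 FPKM, and 7 were within the rule, with a median of 0.08 (-1.30 to 0.33), percentile 82.7. Of 11 genes of ABA synthesis and breakdown, CYP707A4 and CYP707A2, both of breakdown, were 2.98-fold and 2.31-fold higher and 9 were within the rule, with a median of 0.08 (-0.29 to 1.21), percentile 86.1.

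In the list of ion transport and the SOS pathway, 3 of 20 genes were lower and 17 within the rule, with a median of -0.06 (-0.43 to 0.14), percentile 53.7. The lower members were the calcium sensors SOS3, from 14.7 to 5.24 FPKM, and CBL10, from 16.8 to 6.94 FPKM, and RCI2B, whose ratio of -1.04 was -0.97 after centring. SOS1 had a log2 ratio of 0.27 and SOS2 of 0.12. All 12 genes of proline and compatible solutes were within the rule, with a median of -0.30 (-0.54 to -0.04), percentile 5.30, and of 18 aquaporins TIP2;3 was lower, from 15.7 to 5.35 FPKM, and 17 were within the rule, with a median of -0.21 (-0.45 to -0.11), percentile 7.95.

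Clock and flowering genes moved in both directions. Of 15 clock genes, the morning genes LHY, CCA1 and RVE8 were higher, with log2 ratios of 1.99, 1.15 and 1.09, the evening genes FKF1 and ELF4 were lower, with -1.92 and -1.63, and 10 were within the rule. The median was -0.42 (-0.97 to 0.20), percentile 0.50. LHY went from 3.51 to 16.9 FPKM and ELF4 from 79.0 to 24.9 FPKM. Of 11 flowering time genes, 4 were lower, 1 was higher and 6 were within the rule, with a median of 0.08 (-1.20 to 0.57), percentile 86.5. The lower members were FLC and some of its relatives: MAF5 went from 3.23 to 0.188 FPKM, FLM from 25.1 to 10.4 FPKM, MAF4 from 1.63 to 0.1503 FPKM and FLC from 1.24 to 0.0376 FPKM. Their relatives MAF2 and MAF3 were within the rule, with log2 ratios of -0.96 and 0.15. The higher member was FT, the florigen gene, from 0.574 to 4.36 FPKM. FLC shares 64.8% of its sequence with another annotated locus.

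Some jasmonate and defence genes passed the rule, and most of their lists did not. Of 16 jasmonate genes, 3 were lower and 13 within the rule, with a median of -0.37 (-0.98 to 0.12), percentile 0.87. The storage proteins VSP1 and VSP2 went from 222 to 41.6 FPKM and from 966 to 231 FPKM, and JAZ7 was 2.34-fold lower. Of 7 pathogenesis-related genes, 3 were higher and 4 within the rule, with a median of 0.38 (-0.60 to 2.03), percentile 99.2. They were PR1, from 0.391 to 4.67 FPKM, PAD3, an enzyme of camalexin synthesis, 3.81-fold, and PR2, from 2.35 to 6.14 FPKM. Of 10 genes of oxidative stress, CAT2, a catalase, was higher, from 328 to 854 FPKM, 3 were lower and 6 within the rule, with a median of -0.16 (-1.15 to 0.29), percentile 26.8. The superoxide dismutases CSD2 and CSD1 were 2.75-fold and 2.22-fold lower, and APX2, at low levels, had a ratio of -1.02 that was -0.96 after centring. Of 18 heat shock genes, 2 were higher, 2 lower and 14 within the rule, with a median of 0.01 (-0.18 to 0.23), percentile 81.6. Both higher members, HSP23.5 (from 13.9 to 149.6 FPKM) and HSP23.6 (from 0.435 to 3.90 FPKM), encode small heat shock proteins of mitochondria.

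Splicing factors were within the rule in this comparison too. Of 20 SR proteins, 0 were higher and 0 lower, with a median of 0.02 (-0.07 to 0.08), percentile 84.8, and of 12 genes of the spliceosome and Paf1 complex, 0 were higher and 0 lower, with a median of 0.02 (-0.13 to 0.29), percentile 78.7. All 19 nuclear photosynthesis genes were within the rule, with a median of -0.19 (-0.33 to -0.01), percentile 9.33. Of 16 root genes, IRT1 was higher, from 0.867 to 3.12 FPKM, and 15 were within the rule, with a median of -0.02 (-0.33 to 0.31), percentile 69.6. All 5 seed genes were within the rule, at FPKM below 1, with a median of -0.07 (-0.26 to 0.05), percentile 21.4.

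Transcripts of the organelle genomes shifted in skip as a group. Among 83 chloroplast loci above 0 in both groups, 81 were higher in skip, with a median log2 ratio of FPKM of 2.599 (2.49 to 2.70), and among 75 mitochondrial loci 72 were higher, with a median of 2.24 (1.93 to 2.61). Salt had the opposite direction in wild type, where 80 of 83 chloroplast loci and 64 of 71 mitochondrial loci were lower, with medians of -1.25 (-1.36 to -0.94) and -1.24 (-1.37 to -1.05). Chloroplast loci held 2.005% of the summed FPKM in untreated wild type, 1.31% with salt, and 4.44% in skip. Salt-treated wild type is in both ratios, so a low organelle share in that sample would by itself give opposite directions. The shares of untreated wild type and skip do not use it. For mitochondrial loci they were 0.07% and 0.22%, so for both genomes the share was higher in skip. AT2G01021, a gene of 102 nt whose sequence is shared over its whole length with other loci, was listed at 34097 FPKM in wild type and 119043 FPKM in skip. These are 4.63% and 15.1% of the summed FPKM of the 2 groups. Scaling to so short a length raises its FPKM, so they are not shares of the reads.

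**Figure D2:**
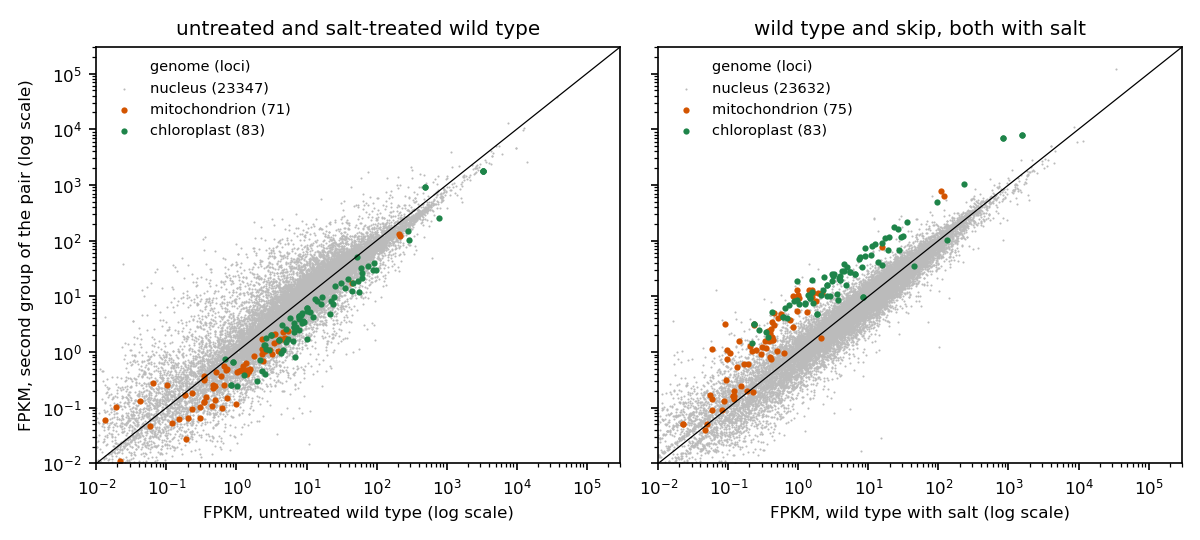
FPKM of every locus above 0 in both groups of a pair, on log axes, for untreated (horizontal) and salt-treated (vertical) wild type on the left and for wild type (horizontal) and skip (vertical) with salt on the right. Grey points are nuclear loci, orange mitochondrial and green chloroplast loci, and the line marks equal values: 80 of 83 chloroplast loci lie below it on the left and 81 of 83 above it on the right.

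Other loci that lead the list in skip are listed at 0 in a group. ATCG00510, ATCG00080, ATCG00760, ATCG00065 and AT5G03204 were listed at 0 in wild type and at 360, 290.2, 93.0, 52.0 and 86.3 FPKM in skip. The rRNA loci AT3G41768 and AT2G01010 were listed at 4608 and 2341 FPKM in wild type and at 0 in skip, as were the chloroplast loci ATCG01180 at 1581 FPKM, ATCG00950 at 1581 FPKM and ATCG00220 at 635 FPKM, MIR397a at 169.1 FPKM, AT5G14560 at 40.7 FPKM and MIR398b at 36.6 FPKM. Of the genes past the rule, 24 higher ones had a 0 in wild type and 34 lower ones a 0 in skip.

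The third question is how the differences in skip relate to the salt response of wild type. Genes that were higher with salt were lower in skip more often than genes at large. Among 26053 genes above 0 in a group, 289 were higher with salt and lower in skip, where independent lists of the same sizes share 68.1, and 109 were lower with salt and higher in skip, against 26.9. In the same directions, 90 genes were higher in both against 42.6, and 87 lower in both against 42.9. Among 15916 genes of at least 5 FPKM in a group, without organellar, rRNA and short features, the opposite directions held 235 genes against 81.3 and 53 against 19.3, and the same directions 88 higher against 35.3 and 84 lower against 44.4. Salt-treated wild type is in both ratios, which by itself favours opposite directions. Simulated on 15871 of these 15916 genes, and not on the low, organellar or short ones, counting noise alone gave a mean of 0.01 genes higher with salt and lower in skip and 0 of the reverse in 100 simulations. Variation between plants was not simulated, so part of the excess may come from the shared group. Over the same 15871 genes, the correlation across genes of the 2 log2 ratios was -0.11 (Pearson) and -0.11 (Spearman), where counting noise of unchanged genes gave -0.46. The covariance was -0.054, against -0.0022 from counting noise, and genes are not independent replicates.

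The relation was graded on the side of the genes higher with salt. Nuclear genes within 0.5 of no salt change had a median log2 ratio in skip of -0.07 (-0.08 to -0.06, 9675 genes). Genes with a salt ratio between 1 and 2 had -0.21 (-0.25 to -0.18, 1081 genes), those between 2 and 3 had -0.36 (-0.43 to -0.29, 403 genes), and those above 3 had -0.39 (-0.51 to -0.27, 263 genes). In the last of these bins 55 genes, 20.9%, were at least 2-fold lower in skip and 9 were higher. For genes lower with salt the medians were not graded in the same way. They were -0.15 (-0.22 to -0.10, 718 genes) for ratios of -2 to -1, -0.12 (-0.22 to -0.03, 180 genes) for -3 to -2 and 0.14 (-0.04 to 0.34, 55 genes) below -3. In the same bins 4.74%, 8.89% and 5.45% of genes were at least 2-fold higher in skip, against 1.05% of the genes within 0.5, and 9.61%, 8.33% and 0% were lower, against 2.53%. BHLH92 is a case of the first kind, at 96.5 FPKM in wild type and 45.5 FPKM in skip. The fixed naming rule took, for opposite directions, AT3G41768, ATCG00220, MIR397a, AT5G14560 and MIR398b as higher with salt and lower in skip, and ATCG00065, AT2G28426, ATCG00580, ATCG00650 and ATCG00040 as lower with salt and higher in skip, all of them rRNA, short or chloroplast features.

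Gene structure was related to the skip ratio. The 1894 nuclear genes with a single exon had a median log2 ratio in skip of -0.37 (-0.40 to -0.35), against -0.06 (-0.06 to -0.05) for 13977 genes with more exons. Classes from 2 exons to 21 or more exons ranged from -0.08 to -0.03. In the salt comparison the single-exon genes had a median of 0.13 (0.07 to 0.18) and the others of 0.01 (0.00 to 0.02). Single-exon genes made up 12 of the 25 stress transcription factors, CBF3, DDF1 and CBF4 among them, and 1 of the 19 LEA and dehydrin genes, which is LTI30.

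**Figure D3:**
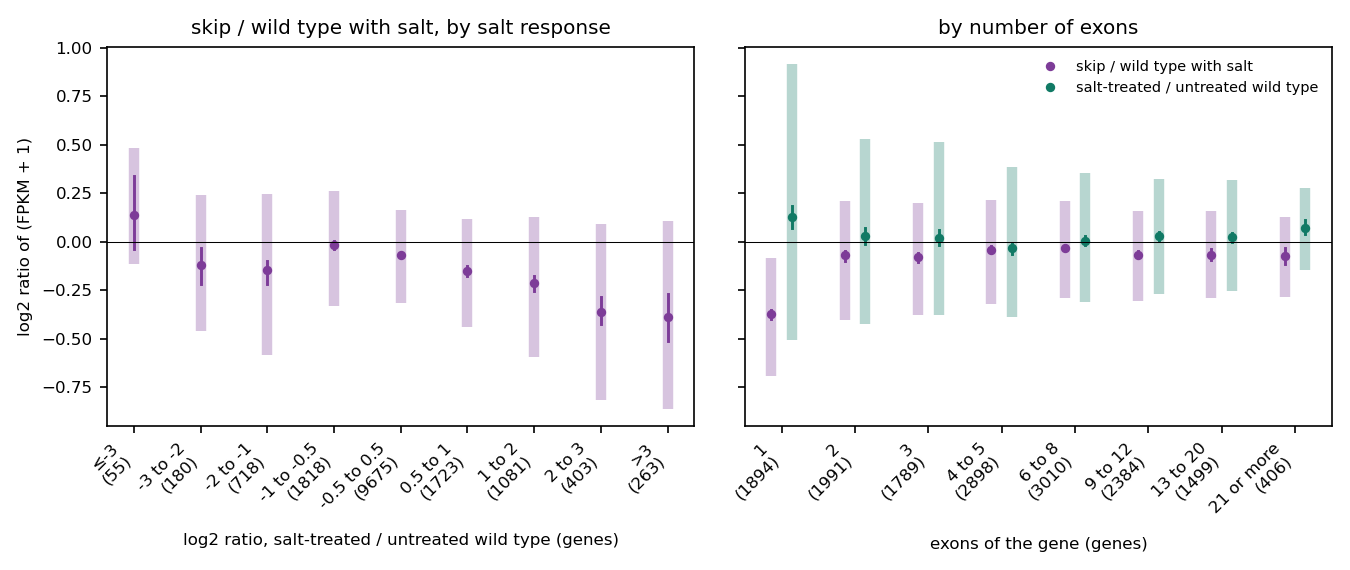
Median log2 ratio of FPKM + 1 (points) with its 95% interval (thin lines) and the quartiles over genes (wide bars), for skip against wild type with salt by the size of the salt response on the left, and for both comparisons by number of exons on the right, with the number of genes in brackets. On the left the median reaches -0.39 for genes with a salt ratio above 3, and on the right single-exon genes lie at -0.37 in skip.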

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

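No paired analysis was possible because the labels merge replicate 1 and replicate 2 of each group into 1 value. For the same reason leaving out replicates, other q thresholds and count tests were not run. The settings that leave out organellar, rRNA and short features or genes listed at 0, and centring within exon classes, were chosen after seeing the data. The pseudocount set the size of the counts. With 0.1, salt gave 3199 higher and 2432 lower genes and skip 1241 and 2047. With 0.01 these were 4286 and 3179, and 2125 and 3154. The construction explains this, since a smaller pseudocount lets genes near 0 pass. Under minimum FPKM of 1 or 5, centring on the median gene, and leaving out the special features or the genes listed at 0, all counts of genes stayed within 1.5 times. In skip, centring gave 635 higher and 739 lower genes. Of the list medians, the SR proteins in skip moved to 0.0899 with centring, and the seed genes in skip to -0.36 with a pseudocount of 0.1, both outside the interval of the reported median, the first by the shift of the median gene. The genes lower with salt and higher in skip numbered 96 with a minimum of 5 FPKM and 53 when organellar, rRNA and short features were left out as well. With the special features, the correlation across genes was -0.16. The skip medians of ion transport, stress transcription factors, root and reference genes lie so near 0 that centring changes their sign. Of the values of named genes under a pseudocount of 0.1 or centring, 302 kept their side of the rule. RBOHF with salt and RCI2B, APX2 and CBF4 in skip missed it by centring, and AZF1 with salt and MAF2 in skip passed it with 0.1.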

Other observations

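The tests of the mitochondrial genes in skip, of length and GC content, of genes without a salt change and of genes with 3 or more exons were fixed before their results were seen, and the other tests here, the gene families and the named genes of the next paragraph were chosen after values had been seen. Genes were grouped by the stem of their symbol, which gave families of at least 8 genes. Of these, 31 with salt and 23 in skip had medians in the outer 1% of matched random lists, against 1.75 if genes of a family moved independently. They need not, and the lists were not matched on exon number, so the excess is no measure of chance. The skip families among them include RTFL (12 of 13 genes with a single exon) and ERF (19 of 24), both with medians below 0. With salt, XTH genes, which remodel cell wall xyloglucan, had 14 of 26 members at least 2-fold lower and a median of -1.05 (-1.51 to -0.18), H2A histone genes (HTA) 4 of 10 lower with -0.82 (-1.17 to -0.04), and MCM genes of DNA replication 2 of 8 lower with -0.83 (-1.13 to -0.28). ERF factors had 13 of 24 members higher with 1.09 (0.39 to 3.18), and MAPKKK kinases 8 of 12 with 1.73 (0.28 to 2.75). In skip, MSRB genes, methionine sulfoxide reductases, had 4 of 9 members lower with -0.71 (-1.46 to -0.11): MSRB7 went from 108.7 to 35.8 FPKM and MSRB8 from 92.4 to 33.0 FPKM, although they share 22.2% and 23.9% of their sequence with each other. Genes with the stem MLP, mostly latex-like proteins, had 5 of 9 members at least 2-fold lower in each comparison. Their medians were -1.19 (-1.92 to -0.16) for salt and -1.0003 (-2.39 to -0.34) in skip, and MLP328 went from 55.6 to 6.76 FPKM in skip. Receptor-like proteins (RLP) had 3 of 37 members at least 2-fold higher in skip and a median of 0.45 (0.28 to 0.75). Genes with the stem CRK, mostly but not all receptor kinases, had 5 of 29 with 0.25 (0.01 to 0.51), led by CRK36 (1.66 to 18.4 FPKM).

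Outside organellar and short features, genes that lead the skip comparison include the light-stress genes ELIP2 (27.4 to 245 FPKM) and ELIP1 (81.9 to 621 FPKM) and the vacuolar transporter ABCC3 (29.4 to 279.7 FPKM) on the higher side. On the lower side XPL1 (AT3G18000), an enzyme of phosphocholine synthesis, went from 14.9 to 0.0284 FPKM, or from about 1331 to about 2 estimated fragments over 12 exons.

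Organelle-genome transcripts were higher in skip and lower with salt. For an error in the shared wild-type sample, only the shares of summed FPKM that do not use it were compared. They were 2.005% in untreated wild type and 4.44% in skip for chloroplast loci, and 0.07% and 0.22% for mitochondrial loci. The higher level in skip thus does not rest on that sample alone, although these groups also differ in salt. The lower level with salt was not tested in this way. A larger share of plastids in the sampled tissue was taken to raise nuclear photosynthesis genes by at least 1 on the log2 scale. Their median was -0.19, with an interval that ends at -0.01, so they did not rise as a list. That bound was set after values had been seen and excludes no plastid cause. Among other families with plastid functions, PTAC genes had a skip median of 0.53 (-0.33 to 0.75) at percentile 100 of matched lists. TOC genes had 0.33 (0.15 to 0.52) at percentile 99.68, and TIC genes -0.02 (-0.20 to 0.39) at percentile 70.1. With salt the percentiles of PTAC, TOC and TIC were 0.04, 1.57 and 2.84. PTAC and TOC genes thus lay on the same side as the chloroplast loci in both comparisons, and a plastid cause stays open. More RNA without poly(A) tails in a library would move both organelle genomes alike, and their medians differed by at most 0.36, but nuclear rRNA, which also lacks such tails, gave no clear direction: AT2G01020 and AT3G41979 were 1.21-fold higher in skip, AT2G01010 and AT3G41768 were listed at 0, which decides nothing, and the short multicopy locus AT2G01021 was 3.49-fold higher. With salt, AT2G01020 and AT3G41979 were 2.15-fold lower, as the organelle loci were, but AT2G01021 did not move (1.003-fold). AT2G01010 fell from 13905 to 2587 FPKM, while AT3G41768, with which it shares 94.3% of its sequence, rose from a listed 0 to 5092 FPKM. Reads may be split between these copies, so their opposite movement is no conflict, and in sum they were lower if the listed 0 holds. All these rRNA and multicopy loci share their sequence with others and the labels do not say how RNA was selected, so a difference in such RNA cannot be told apart from other explanations. A mitochondrial stress response is the other explanation examined: a list of 22 nuclear genes not looked at before, such as the alternative oxidase AOX1A (127 to 543 FPKM) and NAC013 (24.6 to 107.2 FPKM), had 10 members higher and 1 lower, with a median of 0.81 (0.08 to 1.67) at percentile 100 of matched lists. This list was not among those fixed before the data were examined. It was scored in the same samples in which the mitochondrial heat shock genes HSP23.5 and HSP23.6 were higher, so its percentile is no independent check. The same list was higher with salt as well, with a median of 0.34, 9 members higher and percentile 99.52, while the organelle loci were lower there, so whether such a response goes with the organelle transcripts cannot be told apart from a separate change.

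Single-exon genes were lower in skip by 0.32 than genes with more exons (difference -0.32, -0.35 to -0.30). Transcript length and GC content do not account for all of it, because within bins of both the difference was -0.28 (-0.31 to -0.26), below 0 in all 26 bins. An error in the shared wild-type sample would vanish when skip is set against untreated wild type, with the tables joined by the factor of salt-treated wild type, and there the difference was -0.20 (-0.26 to -0.15). Those groups also differ in salt, and in the salt comparison of wild type the same difference was 0.12 (0.06 to 0.17). Whether the smaller size comes from salt or from a part due to such an error cannot be told apart. Salt-responsive genes among them are not the whole cause either, since genes within 0.5 of no salt change gave -0.31 (-0.35 to -0.28). No biological explanation was tested, so the genotype and differences in library preparation both stay open.

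Genes at least 2-fold higher with salt were lower in skip than unmoved genes, by a difference in medians of -0.19 (-0.23 to -0.15). Error without direction in the shared wild-type sample would lift genes lower with salt by as much, and their difference was -0.047 (-0.10 to -0.01). That median argues against such an error as the whole cause, but other values are less clear. The 55 genes below -3 with salt had a skip median of 0.14 against -0.07 for unmoved genes. At 5 FPKM without special features, both opposite directions exceeded independent lists. They held 235 genes against 81.3 (higher with salt, lower in skip) and 53 against 19.3 (the reverse). The same directions did so too, with 84 genes lower in both against 44.4 and 88 higher in both against 35.3. Genes that moved with salt thus passed the rule in skip more often in either direction, so the counts do not decide. A stronger response in that sample alone is not excluded. Single-exon genes made up 25.01% of the salt-raised and 7.73% of the unmoved genes, and among genes with 3 or more exons the difference was -0.11 (-0.15 to -0.06). That interval spans the bound of -0.1 set beforehand, so how much of the pattern comes from gene structure cannot be told apart. A weaker salt response of skip stays open as an untested explanation, since an untreated skip group was not analysed here.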
